A study of Mus musculus with 6 samples.

How the data were processed

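Lymphatic endothelial cells were sorted by flow cytometry from the meninges of male mice aged 6 months, as singlets that were negative for DAPI and CD45 and positive for CD31 and podoplanin. There were 3 libraries from non-transgenic littermates (WT) and 3 from 5xFAD mice, a transgenic model of amyloid deposition, and each library came from a pool of 10 mice, so each was a biological sample. Per the labels' protocols, RNA was extracted with the PicoPure kit and amplified linearly before sequencing. Linear amplification of RNA from few cells multiplies the molecules captured at the start, so a read count has more spread between libraries than its size alone implies.

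The deposited values are a normalized signal, gene counts divided by 1 factor per library. FastQC, Trimmomatic, Salmon, DESeq2 and the mouse build mm10 are named per the submitters' processing notes, without versions or settings. In each column every value was a whole multiple of the smallest value above 0 (100% of values, within 1e-06 of a whole number), so whole reads were recovered by dividing by that value. Factors computed anew from the recovered reads of the listed genes, as the median of ratios, equalled the recovered ones. The table lists 4233 genes. Within the 3 WT libraries and within the 3 5xFAD libraries, no listed gene had an SD of log2(recovered reads + 1) of 2 or more (the highest was 1.99961 in both), while in the 18 choices of 3 libraries that mix the genotypes 380 to 624 genes did. No source used here states such a limit. Because it was applied within genotypes, it keeps genes with a large difference between genotypes only where replicates stay within that limit. Tests that take the spread between replicates as error can then make too many calls for the true grouping. The recovered reads summed to between 7960827 and 13255050 per library over the listed genes. That is a part of each library and not its depth. Intervals on reads cover counting error only.

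Genes with a mean normalized value of at least 10 over the 6 libraries were tested (4152 of 4233), on log2(value + 1). The test was limma 3.58.1 in R 4.3.3 (a moderated linear model with the prior variance following mean level). In the main fit the prior had infinite degrees of freedom, so a gene's own replicate spread had no weight. Each SE, interval and p of that fit reflects the spread typical of genes at that mean level. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. A call was a Benjamini-Hochberg adjusted p under 0.05, and all tests were two-sided. Values of single libraries were compared by exact permutation, which for 3 against 3 cannot go under 0.1. Folds against a group without reads used a floor of 3 reads over the group and are lower bounds. Gene lists (31 lists, 823 symbols, 295 of them matched to the table) were tested with limma's camera at a preset correlation of 0.01 where at least 5 members were tested, with an estimated correlation and with fry beside it. Gene positions are from the GENCODE annotation of GRCm38, the assembly of mm10, and 4190 of the listed genes had 1 position there. Of the 474 names given as Ensembl identifiers, 453 were matched to a symbol.

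The main test, the lists and the rule for named genes were fixed before the data were examined. The rule took App and Thy1 first. It then took, per direction, the 15 genes with the largest fold change among calls whose groups did not overlap, leaving out predicted and clone names. It added up to 4 called members per list, and always Prox1, Flt4, Lyve1, Pdpn, Pecam1 and Ccl21a. Other settings, fixed at the same time, changed the pseudocount, the filter, the prior, the library weights, the scaling, the threshold and the list test. They also left out each library in turn, used the replicate number as a block, and ran edgeR 4.0.16, DESeq2 1.42.0 and voom on the recovered reads. Settings chosen after seeing the data were a test of only the 2824 tested genes that meet the same spread limit in all 20 choices of 3 libraries, a test without genes that lack reads in a group, and a scaling without Malat1 and the mitochondrial rRNAs. On simulated counts built from these libraries with 200 of 4152 genes changed, limma recovered 23.3% of 4-fold changes, 87.5% of 16-fold changes and 100% of 64-fold changes, and called 0.233% of unchanged genes. That simulation did not include the spread limit, noise that differs between genes of similar level, or reads lost to 0. Its rates may therefore be too favourable for these libraries. One list of nuclear RNAs used in the closing section was widened after the planned version had been written, and only the planned version decided the result. App was not analysed here, and some genes that the rule takes are not reported here, though counts include those tested.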

Results

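Gene expression was measured by RNA sequencing in lymphatic endothelial cells sorted from mouse meninges, the membranes around the brain, which hold vessels that drain fluid and immune cells. The 5xFAD strain carries transgenes under the Thy1 promoter and deposits amyloid in the brain. The 3 WT libraries held 11366768, 10263689 and 11934686 recovered reads in the 4233 listed genes. The 3 5xFAD libraries held 13255050, 7960827 and 8573669. The comparison asks how the expression of these cells differs between 5xFAD mice and WT littermates at 6 months.

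No gene of the lymphatic endothelial identity list passed the test, while 78 genes were higher and 186 lower in 5xFAD than in WT (limma, adjusted p under 0.05, 4152 genes tested). Of the 294 genes tested from the fixed lists, 4 were higher: Adamts3, a protease that processes the lymphatic growth factor VEGF-C, Zbp1, Ifit3b and Casp8. The 12 lower ones were Vcam1, an adhesion molecule, Sox17, an endothelial transcription factor, Timp1, an inhibitor of matrix proteases, Robo4, Jag2, Trpv4, Egln3, Ulk1, Nr4a2, Ndufb5, Rrm1 and Mcm5. The table holds only genes with an SD of log2 reads under 2 within each genotype. That still allows wide spread, as for Ulk1 at 1586, 7384 and 449 in the 3 WT libraries. A set of 2824 tested genes, chosen after seeing the data, meets the same limit in all 20 choices of 3 libraries, and so leaves out genes with large differences. In it 1 gene was higher (Malat1) and 0 were lower by limma, with 133 at an unadjusted p under 0.05, against 118 to 136 in the other 9 splits of the libraries. It keeps 87 of the 677 genes at that p, so it decides little.

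**Figure D1:**
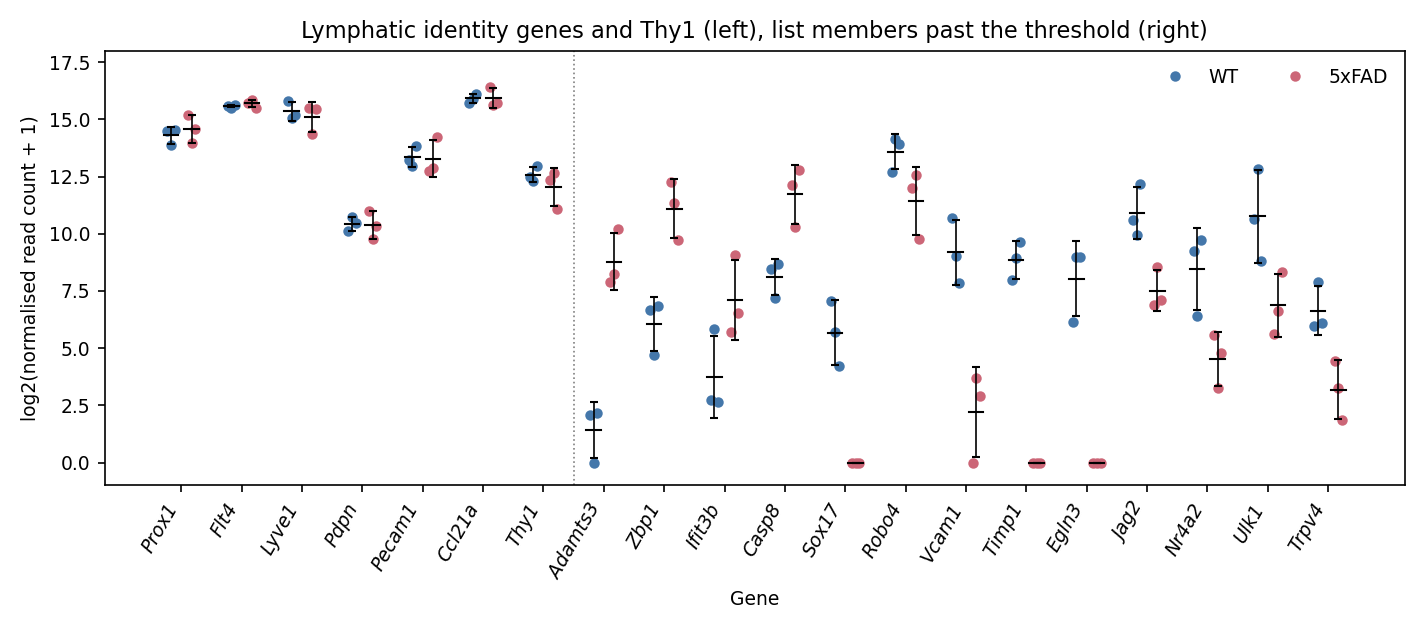
Normalised read count of 20 genes on a log2(value + 1) scale, with 1 point per library, a line at the mean of 3 libraries and bars of 1 SD, WT in blue and 5xFAD in red. Prox1, Flt4, Lyve1, Pdpn, Pecam1, Ccl21a and Thy1 overlap between the genotypes, while Sox17, Timp1 and Egln3 had 0 reads in all 3 5xFAD libraries.

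Thy1, whose promoter drives the transgenes, was at 6253 ± 1456 normalised counts in WT and 4635 ± 2204 in 5xFAD (SD, n = 3 each; log2 fold change -0.55, SE 0.66; limma adjusted p = 0.781). App was not analysed here, so the genotype of the libraries was not checked from their reads.

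Prox1, the transcription factor that sets lymphatic identity, was at 20711 ± 5025 in WT and 26064 ± 10883 in 5xFAD (SD, n = 3), a log2 fold change of 0.28 (95% interval -0.50 to 1.06). Flt4, the VEGF-C receptor, was at 49027 ± 1894 and 53353 ± 6270, a log2 fold change of 0.12 (-0.43 to 0.66). Lyve1, a hyaluronan receptor, had a log2 fold change of -0.25, Pdpn of -0.07, Pecam1 of -0.07 and Ccl21a, a chemokine that guides leukocytes into lymphatic vessels, of 0.01. None of these 6 genes passed the test (limma adjusted p from 0.790 to 0.992). The sign of each of the 6 flips under at least 1 scaling, method or left-out library. Reads of Ccl21a can be shared with the near-identical copies Gm13304 and Gm21541, which makes its level uncertain. How reads were divided between them was not examined here. In the list of lymphatic endothelial identity, 18 of 22 members were measured, and 0 passed by limma, with a median log2 fold change of 0.08. As a list it did pass fry for change in either direction (fry adjusted p = 0.0247), which 14 of 23 lists did.

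The 15 genes with the largest rise included 6 without any WT read. A gene without reads in a whole group has no spread there and passes the spread limit. One with many reads in only some libraries of a group exceeds the limit and is not listed. Evi2 rose at least 418-fold, Etfb, a subunit of the electron transfer flavoprotein, at least 310-fold, and Cdc25a, a cell cycle phosphatase, at least 178-fold. Arrdc1 rose at least 39.7-fold. Fam219aos, an antisense gene whose reads cannot be told from its partner's without strand, also had no WT read (at least 58.1-fold). Adamts3 was at 2.28 ± 1.97 in WT and 575 ± 526 in 5xFAD (log2 fold change 7.36, SE 1.07; limma adjusted p = 9.96e-10; chromosome 5, 89677087 to 89883334). Dnah10, a dynein heavy chain, rose by 6.36 on the log2 scale, Ppfia2 by 5.81 and Acad11, an acyl-CoA dehydrogenase, by 5.33. Itih2 rose by 5.27, Slc25a48, a mitochondrial carrier, by 5.03, and Mynn, a zinc finger protein, by 4.76. Enah, a regulator of actin, had 1 read in WT and 503 in 5xFAD, a ratio of 619 with a counting interval from 111 to 24491. Zbp1, a sensor of nucleic acids, was at 79.8 ± 47.6 and 2766 ± 2011 (log2 fold change 5.03, SE 1.02; limma adjusted p = 4.52e-05). Single libraries carried part of some of these sizes. For the genes named here and in the next 3 paragraphs, each move by over 1.5 times with 1 library left out is given. Without WT 1 the bounds fell to 270 for Evi2, 200 for Etfb, 115 for Cdc25a, 37.5 for Fam219aos and 25.6 for Arrdc1. The Enah ratio fell to 399. Each was 0.644 times its value with all libraries, although WT 1 held no reads of these genes. These falls come from fewer libraries behind the floor or the ratio, not from reads of WT 1. Log2 fold changes without WT 1 were 7.17 for Dnah10, 4.99 for Ppfia2, 4.29 for Acad11, 4.67 for Itih2 and 5.66 for Slc25a48. They were 6.65 for Adamts3, 4.35 for Zbp1 and 5.78 for Mynn without WT 2, and 5.39 for Dnah10 without WT 3, where Enah was at least 157-fold higher. Leaving out 5xFAD 1 gave 5.74 for Dnah10, 4.0 for Mynn and an Enah ratio of 1025, and leaving out 5xFAD 2 gave 7.19 for Dnah10, 5.06 for Ppfia2 and an Enah ratio of 348. Leaving out 5xFAD 3 gave 6.65 for Adamts3, 6.68 for Ppfia2, 5.77 for Slc25a48, 5.72 for Zbp1 and a bound of 38 for Fam219aos.

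The 15 genes with the largest fall included 11 without any 5xFAD read, a form that the spread limit lets through. Hist1h1e, a linker histone, fell at least 850-fold from 916 ± 426 in WT (SD, n = 3), and BC031181 at least 914-fold. Ibtk fell at least 525-fold, B4galt4, a galactosyltransferase, at least 528-fold, and Timp1 at least 473-fold from 510 ± 269. Kcnrg fell at least 450-fold, and Cyp2d22, a cytochrome P450, at least 447-fold. Egln3, a prolyl hydroxylase that acts on hypoxia-inducible factors, fell at least 334-fold, Cdkl2 at least 237-fold, Npl at least 227-fold and Tesk1, a protein kinase, at least 225-fold. Lzic, with 4 reads in 5xFAD against 5275 in WT, changed by -9.21 on the log2 scale. Ppp2r1b, a scaffold subunit of a protein phosphatase, had 3 reads in 5xFAD (WT over 5xFAD ratio 417, counting interval 143 to 2025), Gcdh had 1 (946, 169 to 37401) and Mis12, a kinetochore protein, had 1 (1194, 214 to 47192). Without 5xFAD 1, the library with the most reads, the bounds fell to 481 for Hist1h1e, 518 for BC031181, 297 for Ibtk, 299 for B4galt4, 268 for Timp1 and 255 for Kcnrg. They fell to 253 for Cyp2d22, 189 for Egln3, 134 for Cdkl2, 129 for Npl and 127 for Tesk1. The ratios fell to 236 for Ppp2r1b and 536 for Gcdh, and Mis12 was at least 226-fold lower. Apart from Mis12, each value was 0.567 times that with all libraries, although 5xFAD 1 held no reads of these genes. These falls come from fewer libraries behind the floor or the ratio, not from reads of 5xFAD 1. Without WT 3 the bounds were 447 for BC031181, 249 for Kcnrg and 135 for Npl, and the Mis12 ratio was 392. Lzic was at -8.55 without WT 1, -10.12 without WT 2 and -10.06 without 5xFAD 2, and Gcdh was at least 222-fold lower without 5xFAD 2.

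The 4 higher and 12 lower list genes were spread over 15 of the 31 lists. In the pan-endothelial list 2 of 18 members fell, Sox17 (67.6 ± 59.3 in WT, at least 62.7-fold lower) and Robo4, an endothelial guidance receptor (13415 ± 5912 and 3674 ± 2640; limma adjusted p = 0.0151). Vcam1 (802 ± 755 and 6.26 ± 6.09; log2 fold change -6.98, SE 1.07; limma adjusted p = 9.41e-09; chromosome 3, 116109949 to 116129688) was the 1 called member of the lists of junctions and adhesion (17 tested), inflammatory genes (5 tested) and leukocyte trafficking (14 tested). In the type I interferon response 2 of 11 members rose, Zbp1 and Ifit3b (log2 fold change 3.35; limma adjusted p = 0.0305), and 7 of the 11 had a positive log2 fold change (median 0.81). Of members that did not pass, Ifit2 and Trim25 had log2 fold changes of 2.43 and 1.55, and Isg15 and Oasl2 of -1.64 and -1.57. Casp8, an initiator caspase, was the 1 called member of 12 in apoptosis and senescence (log2 fold change 3.62), and Adamts3 the 1 of 20 in VEGF-C signalling and lymphangiogenesis, where 11 of the 20 had a negative log2 fold change (median -0.20). In the proliferation list 2 of 3 members fell, Rrm1, a ribonucleotide reductase subunit (-4.87), and Mcm5, a replication helicase subunit (-3.34). With single libraries left out, the Sox17 bound fell to 32.3 (WT 1) and 35.5 (5xFAD 1), and Robo4 was at -1.31 (5xFAD 3). The library 5xFAD 1 held no Sox17 reads, so the fall without it comes from fewer libraries behind the floor. Vcam1 was at -6.22 (WT 1), -7.64 (WT 3), -5.87 (5xFAD 1) and -7.73 (5xFAD 2), and Zbp1 at 4.35 (WT 2) and 5.72 (5xFAD 3). Ifit3b was at 4.39 (WT 2), 4.06 (5xFAD 1) and 2.36 (5xFAD 2), Casp8 at 4.35 (5xFAD 2), and Rrm1 at -5.90 (WT 1), -4.17 (WT 2) and -5.81 (5xFAD 2).

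Single members fell in 7 further lists. They were Timp1 in matrix (18 tested), Egln3 in hypoxia and glycolysis (14) and Ulk1, a kinase that starts autophagy, in lysosome and autophagy (17; log2 fold change -3.90). Jag2, a Notch ligand, in TGF-beta, BMP, Notch and Wnt signalling (10; -3.40) and Trpv4, a calcium channel, in valve and contractile regulation (10; -3.46) also fell. So did Nr4a2, an immediate early transcription factor, in the dissociation list (5; -3.91) and Ndufb5, a subunit of respiratory complex I, in nuclear oxidative phosphorylation (10; -3.37). With single libraries left out, Ulk1 was at -2.86 (WT 2), -4.87 (WT 3), -3.27 (5xFAD 1) and -4.64 (5xFAD 3), and Jag2 at -2.77 (WT 3). Trpv4 was at -2.83 (WT 2), -4.08 (5xFAD 1) and -2.80 (5xFAD 3), Nr4a2 at -4.94 (WT 2), -3.28 (WT 3) and -3.27 (5xFAD 2), and Ndufb5 at -2.35 (5xFAD 1) and -4.27 (5xFAD 2). Adjusted over the list alone, the counts were the same except for 2 lower in matrix and 1 higher beside the 1 lower in hypoxia, lysosome and dissociation. No member passed by limma in cytosolic ribosomal proteins (36 tested), mitochondrially encoded genes (12), amyloid processing and clearance (12), Alzheimer disease risk (12), antigen presentation (11), the unfolded protein response (11) or cholesterol synthesis (4).

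As whole lists, 0 of 23 passed camera (adjusted p from 0.956 to 0.989), 0 had an unadjusted p under 0.05 and 0 passed with an estimated correlation. Fry gave 6 lists with an unadjusted p under 0.05 and 0 adjusted for movement in 1 direction. For change in either direction, without comparing a list with other genes, 14 of the 23 passed fry adjusted, among them matrix (fry adjusted p = 0.00102), type I interferon response (0.00176), pan-endothelial (0.00176) and lymphatic endothelial identity (0.0247). No member of the blood endothelial (7 tested), meningeal fibroblast (10), mural (4), leukocyte (2), erythroid and platelet (1) and neural (2) lists passed by limma, and no bone and cartilage gene was tested. The mean log2 level of the 2 neural genes was 8.02 ± 1.18 in WT and 9.84 ± 0.80 in 5xFAD (SD, n = 3; exact permutation p = 0.2), and that of the blood endothelial list was 10.32 ± 0.50 and 9.65 ± 0.12 (exact permutation p = 0.1, the smallest possible). The fibroblast list was at 11.87 ± 0.38 and 11.59 ± 0.04 (exact permutation p = 0.1). This p was not particular to these lists. Others that reached it were pan-endothelial (11.79 ± 0.22 and 11.24 ± 0.14), matrix and, with a rise, type I interferon response (8.69 ± 0.16 and 9.53 ± 0.40), among more. Of the 3 male-specific genes measured, 0 passed by limma.

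The libraries differed in how many listed genes had no reads, with 31.0 ± 9.5 in WT and 107 ± 35 in 5xFAD (SD, n = 3; exact permutation p = 0.1, two-sided). All 3 WT libraries lacked reads for 11 genes, of which 10 were called, and all 3 5xFAD libraries lacked reads for 54, of which 50 were called. Malat1, a nuclear noncoding RNA, made up 4.22 ± 0.38% of recovered reads in WT and 5.49 ± 0.75% in 5xFAD (exact permutation p = 0.1), and was 1.42-fold higher by normalised count. Mitochondrial ribosomal RNAs made up 16.1 ± 1.1% and 16.7 ± 3.5% (exact permutation p = 0.8). Among the 100 most abundant genes, 2 were called, Malat1 and the mitochondrial rRNA mt-Rnr1 (1.20-fold higher), and the median absolute log2 fold change was 0.33. Among the 2824 genes within the spread limit in all 20 choices, the mt-Rnr1 call was lost (limma adjusted p = 0.920) and the Malat1 call was kept (limma adjusted p = 0.0120). How the Malat1 call depends on the variance prior is given in the closing section. With quantile normalization the Malat1 call was lost (log2 fold change 0.17, limma adjusted p = 0.0797) and mt-Rnr1 turned to -0.17. That method sets values by rank alone, and these mirrored values do not measure the size of either change. Recentred on the median log ratio, Malat1 was at 0.54 (limma adjusted p = 6.91e-07) and mt-Rnr1 at 0.30. Scaled to the same total, they were at 0.37 (limma adjusted p = 0.0021) and 0.13.

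**Figure D2:**
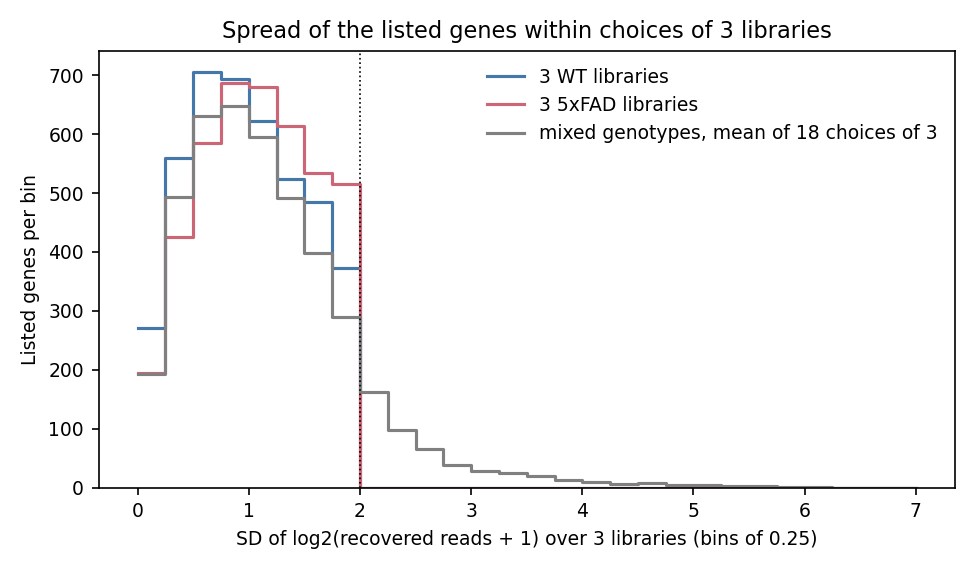
Number of listed genes by the SD of log2(recovered reads + 1) over 3 libraries, in bins of 0.25, for the 3 WT libraries, the 3 5xFAD libraries and the mean of the 18 choices of 3 that mix genotypes. No gene lies at or above an SD of 2 within a genotype, while 380 to 624 do in the mixed choices.

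Groups did not overlap for 72 of the 78 higher and 175 of the 186 lower genes, and for 18.1% of all tested genes. Chance gives 10% without the spread limit, while unchanged genes simulated under the limit gave 14 to 20.3%, depending on the noise assumed. Quantile normalization moved the balance to 120 higher and 160 lower. DESeq2 on recovered reads gave 163 higher and 264 lower, and a mean of at least 50 left 49 and 116. The calls of Casp8, Ifit3b, Jag2, Mcm5, Ndufb5, Nr4a2, Robo4, Trpv4 and Ulk1 were lost when at least 1 single library was left out (limma adjusted p up to 0.338).

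**Figure D3:**
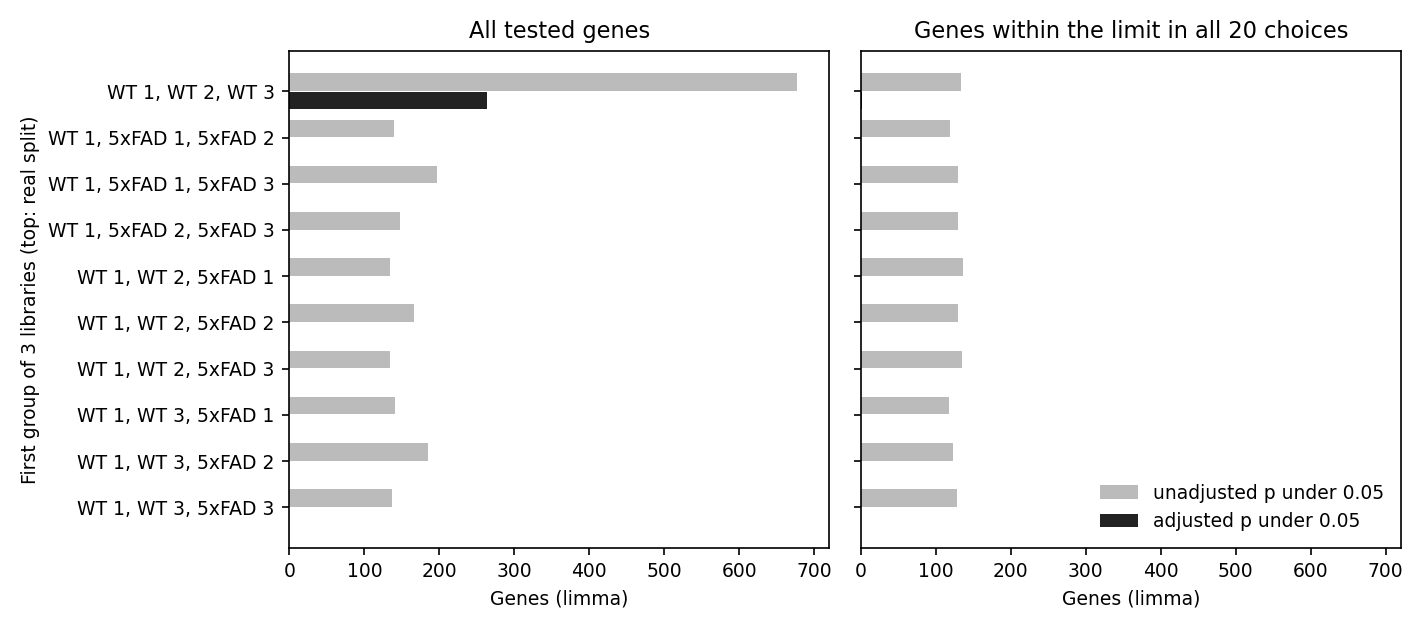
Genes with an unadjusted p under 0.05 (grey) and an adjusted p under 0.05 (black) by limma for the 10 splits of the 6 libraries, with the real split at the top, in all 4152 tested genes (left) and in the 2824 within the spread limit in all 20 choices (right). The real split has 677 and 264 genes on the left, and 133 and 1 on the right. On the left the spread limit is met only within the genotypes, which favours the real split in advance.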

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

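Tests on the equal spread limit, on genes with reads in both groups and on scaling without Malat1 and mitochondrial rRNA were chosen after seeing the data. The 78 higher and 186 lower genes became 49 and 116 with a mean of at least 50 (fewer genes tested), 120 and 160 with quantile normalization, 134 and 229 at an adjusted p under 0.1 (a looser threshold) and 163 and 264 with DESeq2; the cause was not tested for quantile normalization and DESeq2. Under the equal limit 1 gene was higher and 0 lower, and 1 list, amyloid processing and clearance, passed camera (adjusted p = 0.0446, and 0.629 with an estimated correlation) where 0 had. Leaving out single libraries gave 54 to 85 higher, 143 to 192 lower and 0 to 0 lists past camera. With the replicate block there were 80 higher, 190 lower and 0 lists; same-numbered libraries did not deviate together (correlations 0.00247, -0.0157 and -0.0126), and 0 of 6 correlated best with their own number. Scaling to the same total moved the median log2 fold change from -0.02 to -0.14.

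Of the 42 called named genes, 33 kept their call with every library left out in turn. Lost calls (limma adjusted p up to 0.338) were Casp8 without 5xFAD 3, Ulk1 without WT 2 or 5xFAD 1, Robo4 without WT 2, WT 3 or 5xFAD 3, and Jag2 without WT 3, 5xFAD 1 or 5xFAD 3. Lost too were Trpv4 without WT 2, 5xFAD 2 or 5xFAD 3, Nr4a2 without WT 1, WT 3 or 5xFAD 2, and Ifit3b without WT 1, WT 3, 5xFAD 2 or 5xFAD 3. The last were Mcm5 without WT 1, WT 2, 5xFAD 2 or 5xFAD 3, and Ndufb5 without WT 2, WT 3, 5xFAD 1 or 5xFAD 3. In the order named, the highest limma adjusted p was 0.0738, 0.194, 0.219, 0.178, 0.210, 0.0997, 0.305, 0.165 and 0.338. Robo4 was also lost without the trend and with DESeq2, Ndufb5 and Mcm5 with quantile normalization and edgeR, Trpv4 with quantile normalization, and Mcm5 among genes with reads in both groups.

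The log2 fold changes of uncalled identity genes changed sign. Flt4 went to -0.294 with quantile normalization and -0.0050 with the same total. Under those settings Ccl21a went to -0.064 and -0.112, and without mitochondrial rRNA and Malat1 to -0.077. Pecam1 went to 0.044 with DESeq2. With single libraries left out, Prox1 ranged from -0.031 to 0.577, Lyve1 from -0.446 to 0.123, Pdpn from -0.387 to 0.225, Pecam1 from -0.534 to 0.196 and Ccl21a from -0.247 to 0.156. The cause was not tested.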

Other observations

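The tests on the spread limit, its simulation, the splits of the libraries and the variance prior of Malat1 were chosen after the results were seen. Of the 12 measured genes of amyloid processing and clearance, 11 had a negative log2 fold change, the same 11 under all 4 scalings tried, and 0 passed by limma. Ece1, a protease that can degrade amyloid beta, was at 38061 ± 5016 in WT and 22131 ± 7420 in 5xFAD (SD, n = 3; log2 fold change -0.84; limma adjusted p = 0.173), and Lrp1, a receptor that binds it, was at 14850 ± 3151 and 9320 ± 5561 (-0.81; limma adjusted p = 0.468); both were picked after their values were seen. The list did not pass camera among all tested genes (adjusted p = 0.956), and its pass under the equal spread limit was lost with an estimated correlation (adjusted p = 0.629).

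The first pattern is the 264 genes past the threshold, a count that 1 of the 10 splits, the real one, reached. The highest of the others gave 0, and 10 splits are too few for a share under 0.05. The spread limit is met only within the genotypes, while mixed choices of 3 libraries have 380 to 624 genes at or over it. That favours the real split in advance, so this contrast cannot decide. In genes under the equal limit the real split had 133 genes at an unadjusted p under 0.05, against 118 to 136 in the other 9, but that set keeps 87 of the 677 such genes of the real split, so this says little about changes of moderate size. Unchanged genes simulated under the limit gave a median of 18 calls over 25 runs with 1 noise level per class of expression, 96 (61 to 128) with noise that differs between genes, and 171, 217, 244, 305 and 431 when read counts also drop to 0 in any library at a rate of 10, 12, 14, 16 and 20%. Where noise differed between genes, the lowest class had no finite estimate and was given that of the next class. Yet 160 of the 264 real calls were in the lowest quartile of mean level, so these counts rest on a borrowed noise level. At 14% (210 to 282 calls) 64 genes lacked all reads in a group and the mean correlation between the groups was 0.732. These values were 65 and 0.747 in these libraries, 45 and 0.744 at 12% (154 to 268 calls) and 184 and 0.634 at 20%. The rates of 12, 14 and 16% were added after the result, to lie near the real values, so a near match was arranged. Loss was set equal in all libraries, so the runs do not model the 54 genes without reads in 5xFAD against 11 in WT. By the number of calls alone, the limit may account for part or all of them, though the noise and the rate of loss are assumed. A difference between the genotypes stays open, since the equal limit removes genes with large differences.

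The second pattern is the 54 genes without reads in 5xFAD, against 11 in WT. The spread limit favours this form, since it passes genes without reads in a whole group. It removes those with many reads in only some libraries of a group. Sequencing depth as the cause was tested only through the reads over the listed genes, which are a part of each library and not its depth. With every library thinned to the reads of the shallowest one, 54 of the 54 genes kept reads in all 3 WT libraries. The difference in those reads was too small to empty these genes by sampling. With a median WT mean of 66.9 in these genes, that outcome was likely in advance, so the thinning decides little. The library 5xFAD 1 held 13255050 such reads, against at most 11934686 in a WT library, and none in these 54 genes. For that library this argues against the number of those reads as the cause. Thinning also treats each read as a separate molecule, which amplified reads are not. Fewer captured molecules in the 5xFAD libraries cannot be told apart from a genotype effect. Under the equal limit the ratio of genes at 0 was 1 after thinning. That set, chosen after the data were seen, holds only 14 of the 216 genes with a 0 in any library (6.48%), which makes the test void, and the genotype itself remains open.

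The third pattern is Malat1, 1.42-fold higher. Whether its call comes from a prior variance set by few genes at the highest levels is open. Without the trend its log2 fold change of 0.49 was the same, its SE rose from 0.0931 to 0.820 and its limma adjusted p to 0.870. At the SE of a typical gene (0.895), though, such a fold cannot pass whatever the cause. With a robust trend the call was kept (SE 0.155, limma adjusted p = 0.0271). Both fits with the trend took its SE from the prior alone, so the robust fit is no separate check on the prior. Its own libraries give an SE of 0.128, above the 0.0931 of the main fit. A larger share of nuclear RNA in the 5xFAD libraries stays open: of 9 planned nuclear RNAs 2 were measured, Neat1 (0.62) and Airn (-1.74), with a median log2 fold change of -0.56, too few to decide. A list widened to 17 after planning, which adds RNAs that are not retained in the nucleus, had 5 measured and a median of 0.62, and it was not used to decide. A change of Malat1 with the genotype also remains open.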
